A study of Arabidopsis thaliana with 9 samples.

How the data were processed

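Per the labels, seedlings were grown with 16 h of light at 22 °C and 8 h of darkness at 18 °C and were collected at 2 weeks of age. RNA was extracted with an RNeasy Plant Mini Kit, polyadenylated RNA was isolated with a Dynabeads mRNA Purification Kit, and libraries were made with a NEXTflex RNA-Seq Kit. The labels do not give the hour of collection. The processing notes name fastp 0.23.2, HISAT2 2.2.1, StringTie 2.1.7 and the TAIR10 genome, without their order or settings. The FPKM values were computed by the authors and deposited as 1 table with 9 libraries, which was the starting point here. Strandedness, read length and read numbers were not given in the sources used here. Raw reads were not analysed here.

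The deposited table held 37929 lines for 37898 genes. AT1G58520 was on 32 lines, and the line with a value above 0 in every library was kept. All 37898 gene identifiers were found in the TAIR10.1 reference annotation, which supplied coordinates, strands, symbols, products and gene types. Columns were assigned to samples by name, with 0 columns of other samples. The table held 4 ribosomal RNA genes and 0 organelle genes. Genes were taken as transposable elements from the product text of any gene or the note text of pseudogenes, which gave 101 genes, 19 of them tested. That rule was corrected after its first members had been seen, because free-text notes of other genes had matched.

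The depth of each library was estimated from the deposited values, because low FPKM values times gene length fall on steps whose size gives the aligned amount. Between 63.0% and 71.7% of the low values lay within 0.1 of a step. At the estimated depth, an FPKM of 1 in a gene of 1.5 kb rests on 1521 to 1873 aligned bases.

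There were 3 groups of n = 3 libraries, Col-0, nrpd1-3 and nrpe1-11. The comparisons were nrpe1-11 against Col-0, nrpd1-3 against Col-0, nrpe1-11 against nrpd1-3, and the overlap of the changes against Col-0. Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were kept (18212 genes). Log2(FPKM + 1) was fitted in limma 3.58.1 under R 4.3.3 with 1 mean per genotype over all 9 libraries. The tests were two-sided moderated t tests after empirical Bayes with an intensity trend, on 14.8 degrees of freedom, adjusted by the Benjamini-Hochberg method over all tested genes. A gene was called at an adjusted p under 0.05, without a fold threshold. Groups that did not overlap were counted beside the calls. With 3 libraries against 3, chance gives 10% of genes without overlap.

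Of 21 gene lists with 269 genes, fixed before the data were examined, 20 had at least 5 tested members and were tested with camera, which compares a list with the other genes, at a preset correlation of 0.01. Camera with an estimated correlation and fry, which tests for movement within the list, were run beside it, each adjusted over the lists of a comparison. Members were also counted after adjustment over the list alone. The list of silenced or methylation-sensitive genes had 4 tested members and was only counted. Transposable element genes were compared with the other tested genes by Fisher's exact test. Copy sums added the FPKM of near-identical genes.

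The genes named were set by a rule fixed before the data were examined. NRPD1 and NRPE1 were always named. Among called genes without overlap, the 8 largest changes in each direction were named. From each list up to 3 called members with the smallest adjusted p were named, or the 1 member with the smallest p as a value. Where fewer than 5 genes passed, the 6 with the smallest p were named as values. Genes picked otherwise are marked as such. Genes that overlap another annotated locus are named as uncertain.

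For the overlap of the changes against the shared Col-0 libraries, 100 sets of libraries without any effect were simulated from the residual spread, and their correlation, covariance and share of equal signs were taken the same way. The workflow was tested on simulated data. Genes to change were drawn from those with a mean log2(FPKM + 1) above 2. Members of the jasmonate list were also lowered by 1, whatever their level. The recovery rates therefore do not describe low genes. Among 17880 simulated genes, nrpe1-11 against Col-0 recovered 20 of 67 genes changed by 0.5 on the log2 scale, 84 of 93 changed by 1 and 66 of 66 changed by 2, with 10 of 17650 unchanged genes called. The simulated comparison of nrpd1-3 with Col-0, which held no changes, called 0 genes, and that of nrpe1-11 with nrpd1-3 called 17 of 17650 unchanged genes.

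Alternatives were a pseudocount of 0.1, no expression filter, a mean FPKM of at least 5, median-ratio rescaling, quantile normalization, the replicate number as a block, a fit of only the 6 libraries compared, robust empirical Bayes, a threshold of at least 2-fold, and each library left out in turn. Rescaling to the protein-coding sum was added after ribosomal RNA was seen to take a large and uneven share. Tables and figures were made with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.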

Results

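Polyadenylated RNA from 2-week-old Arabidopsis thaliana seedlings was measured by RNA sequencing in 3 genotypes, with the treatment labelled Mock throughout: wild-type Col-0, libraries labelled nrpd1-3 (a mutant of NRPD1, the largest subunit of RNA polymerase IV) and libraries labelled nrpe1-11 (a mutant of NRPE1, the largest subunit of RNA polymerase V). Each genotype had n = 3 libraries. The deposited values were FPKM per gene for 37898 genes, and 18212 genes with an FPKM of at least 1 in at least 3 of the 9 libraries were tested. Between 16802 and 17604 genes per library reached an FPKM of 1. Read numbers were not used here. The spacing of the low FPKM values put the aligned sequence at 1.23, 1.01 and 1.22 gigabases in the Col-0 libraries, 1.25, 1.18 and 1.09 in nrpd1-3 and 1.06, 1.12 and 1.21 in nrpe1-11. Ribosomal RNA genes took 18.5 ± 2.52% of the FPKM in Col-0, 16.6 ± 2.85% in nrpd1-3 and 18 ± 1.06% in nrpe1-11 (mean ± SD). Their highest share, 21.4%, was in Col-0 replicate 2.

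All fold changes below are differences of mean log2(FPKM + 1), so they understate the changes of genes with low FPKM. Values are means ± SD of n = 3 libraries, tests are moderated t tests in limma, and p-values were adjusted over the 18212 genes. The labels do not say whether the 3 libraries of a genotype came from separate plants or pools, so the p-values measure only the spread between these libraries. The median change of all tested genes was 0.17 in nrpe1-11 against Col-0, 0.11 in nrpd1-3 against Col-0 and 0.06 in nrpe1-11 against nrpd1-3, and the changes and calls below were tested against 0 and still hold that shift, so a small rise in nrpe1-11 may reflect it. Strandedness was not given in the sources used here, so a gene that overlaps another locus may carry reads of that locus. The first principal component held 47.9% of the variance. It placed the nrpe1-11 libraries at 39.6 to 42.8 and the other 6 libraries at -27.1 to -17.1. The second component, with 15.5% of the variance, placed Col-0 replicate 2 at -38.5 and the other libraries at -6.62 to 22.3. That library also had the lowest share of FPKM in protein-coding genes (67.0%) and the highest share in its 10 largest genes (35.7%). Correlations of log2(FPKM + 1) between Col-0 and nrpd1-3 libraries were 0.969 to 0.98, and between Col-0 and nrpe1-11 libraries 0.932 to 0.947.

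What the libraries held for the mutated genes themselves came first. NRPD1 had 0.565, 0.489 and 1.06 FPKM in the Col-0 libraries and 0.674, 0.670 and 0.947 in the libraries labelled nrpd1-3, so its RNA was not lower where the label names its mutant (0.764 ± 0.159 against 0.703 ± 0.307 FPKM, log2 fold change 0.06, SE 0.222, adjusted p = 0.948 in limma). That small value was 0.01 without Col-0 replicate 1, -0.03 without Col-0 replicate 2, 0.21 without Col-0 replicate 3, 0.10 without nrpd1-3 replicate 1, 0.10 without nrpd1-3 replicate 2 and -0.01 without nrpd1-3 replicate 3. NRPE1 had 0.831, 0.843 and 0.863 FPKM in Col-0 and 0.624, 0.254 and 0.339 in nrpe1-11, a log2 fold change of -0.40 (SE 0.215, adjusted p = 0.196) with each nrpe1-11 library below each Col-0 library. In the libraries labelled nrpd1-3, NRPE1 had 1.4, 1.28 and 1.19 FPKM (log2 fold change 0.31 against Col-0, adjusted p = 0.708). ROS1, which encodes a DNA demethylase whose RNA depends on methylation near its promoter, had 4.79, 3.42 and 3.89 FPKM in Col-0, 4.41, 4.44 and 4.22 in the libraries labelled nrpd1-3 and 0.980, 0.887 and 1.11 in nrpe1-11. ROS1 fell by 1.33 on the log2 scale in nrpe1-11 (SE 0.175, adjusted p = 6.92e-05). Its value in the libraries labelled nrpd1-3 was 0.10 (95% interval -0.275 to 0.472, adjusted p = 0.883). ROS1 was singled out for nrpd1-3 after its values were seen. Neither the labels nor these values settle whether the libraries labelled nrpd1-3 lack NRPD1 function, and each later use of them carries the label as given.

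**Figure D1:**
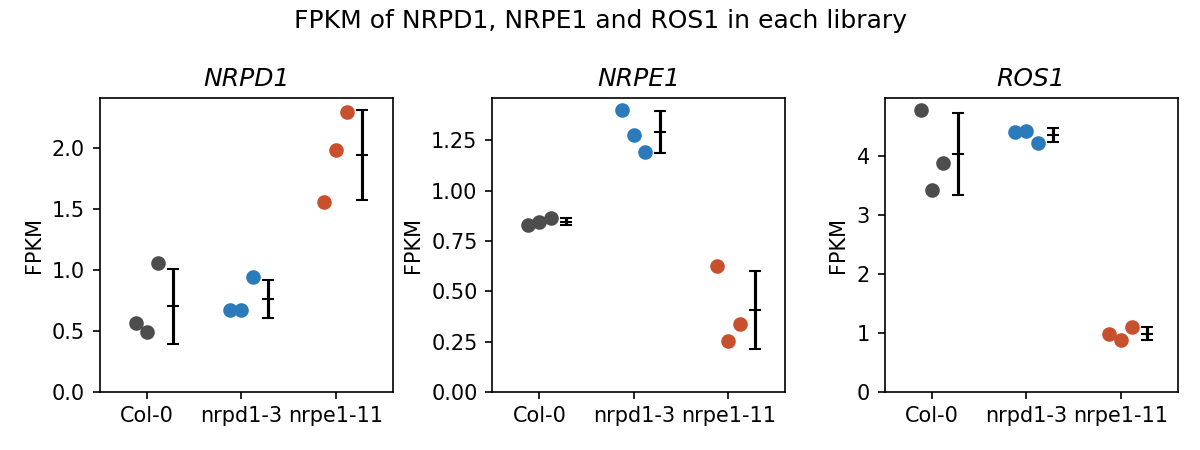
FPKM of NRPD1, NRPE1 and ROS1 in each of the 9 libraries, with 3 libraries per genotype.

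The comparison of nrpe1-11 with Col-0 asked which RNAs differ when the RNA polymerase V subunit is mutated. The largest falls included light-harvesting and defense genes. LHCB2.1, a light-harvesting protein of photosystem II, fell from 298 ± 28.9 to 16.1 ± 1.05 FPKM, an 18.6-fold ratio (log2 fold change -4.13, SE 0.092, adjusted p = 2.72e-13), and LHCB1.1 fell from 973 ± 48.0 to 62.4 ± 4.67 FPKM (-3.94). The glutathione transferase gene GSTF6 fell from 440 ± 57.1 to 28.5 ± 0.660 FPKM, the chitinase gene AT2G43620 from 56.4 ± 6.24 to 2.6 ± 0.909, and the camalexin gene CYP71A13 from 33.5 ± 5.26 to 1.22 ± 0.0517. FRK1, a receptor kinase induced by flagellin, fell from 19.1 ± 3.19 to 0.381 ± 0.337 FPKM (log2 fold change -3.88, adjusted p = 1.56e-09). The berberine-bridge type oxidase gene AT1G26380 fell from 37.8 ± 1.38 to 1.73 ± 1.07 FPKM, and AT5G44575, of unknown function, from 15.1 ± 0.614 to 0.271 ± 0.0611. In each of these 8 genes every nrpe1-11 library lay below every Col-0 library, which the rule that named them required. CYP71A13 and FRK1 overlap a locus on the other strand and are uncertain to that extent.

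Near-identical copies share reads, so copy sums were compared for these genes. The summed FPKM of the LHCB2 copies was 704 in Col-0 and 51.1 in nrpe1-11 (13.8-fold), that of GSTF6 and GSTF7 766 and 64.5 (11.9-fold), and that of CYP71A12 and CYP71A13 85.7 and 5.03 (17-fold). The LHCB1 copies summed to 9966 and 6331 FPKM (1.57-fold), so the fall of LHCB1.1 was far larger than that of its family. PDF1.2 and PDF1.3 summed to 65.8 and 10.8 FPKM (6.10-fold), and the RBCS copies to 5983 and 4255 (1.41-fold).

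The largest rises in nrpe1-11 were mostly in transcripts without an assigned function. AT4G02795, an uncharacterized RNA, rose from 0.836 ± 0.731 to 29.7 ± 2.39 FPKM (log2 fold change 4.16, SE 0.346, adjusted p = 6.3e-07). KELP, a transcriptional coactivator gene, rose from 47.3 ± 12.1 to 245 ± 8.82 FPKM (2.38, adjusted p = 3.27e-08). AT5G41830, which encodes a leucine-rich repeat-like protein, was listed at 0 in each Col-0 library and at 5.69, 5.31 and 5.27 FPKM in the nrpe1-11 libraries. The RSU1 pseudogene (2.11), the noncoding RNAs AT5G38005 (2.1) and AT1G67105 (2.08), the spliceosomal RNA U2.1 (2.02) and AT5G23115 (2.13), of unknown function, also rose. AT4G02795, RSU1 and U2.1 overlap another locus on the same strand and KELP on the opposite strand, so the source of their reads is uncertain.

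In all, 3955 of 18212 genes (21.7%) were called in nrpe1-11 against Col-0 at an adjusted p under 0.05 in limma, 2581 higher and 1374 lower. Among the 660 that changed at least 2-fold, 126 were higher and 534 lower, and among the 113 that changed at least 4-fold, 8 were higher and 105 lower. The 3 nrpe1-11 and 3 Col-0 libraries did not overlap in 7170 genes, or 39.4%, where chance gives 10%. The number of genes called higher also fell to 1672, 1666 and 1585 without nrpe1-11 replicates 1, 2 and 3. The number called lower was then 1150, 1151 and 1173. The share of called genes that were higher, 65.3%, depended on scaling: 35.3% after median-ratio rescaling (1183 higher, 2167 lower), 46.7% after quantile normalization (1625 and 1858), 60.7% after scaling to the protein-coding sum (2502 and 1617) and 53.4% without Col-0 replicate 2 (1646 and 1438). The 7 gene lists that camera called, described next, kept their lower direction under each of these scalings.

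Jasmonate and ethylene defense genes fell as a group in nrpe1-11. LOX2, which starts jasmonate synthesis, fell from 44.6 ± 1.51 to 5.22 ± 0.275 FPKM (log2 fold change -2.87, SE 0.099, adjusted p = 2.99e-11 in limma). The defensin gene PDF1.2C fell from 11.4 ± 0.858 to 0.928 ± 0.157 FPKM and the jasmonate synthesis gene AOC2 from 40.6 ± 7.10 to 5.40 ± 1.16. Of 26 tested members, 19 were lower, 1 was higher (COI1, the jasmonate receptor, 0.40, adjusted p = 0.0451) and 6 were not called, with 21 called when adjusted over the list alone. JAZ8, a repressor of jasmonate responses, was listed at 0 in each nrpe1-11 library and at 1.37, 2.31 and 0.916 FPKM in Col-0. COI1 and JAZ8 were picked after the values were seen. The median log2 fold change of the list was -1.20, and the list lay below the other genes in camera (adjusted p = 1.37e-23). Camalexin and indole glucosinolate genes were also lower. CYP71A12 fell from 52.2 ± 6.01 to 3.81 ± 0.602 FPKM (-3.47, adjusted p = 4.32e-11), and CYP79B2, which makes the first shared intermediate from tryptophan, from 50.7 ± 0.569 to 8.44 ± 0.987. In that list 9 of 10 members were lower and 1 was not called, also 9 when adjusted over the list alone, with a median of -2.27 (camera adjusted p = 1.44e-22). COI1 overlaps a locus on the opposite strand and is uncertain.

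Genes of pattern-triggered immunity and early wounding responses were also lower in nrpe1-11. NHL10, a membrane protein gene induced by flagellin, fell from 12.4 ± 0.699 to 1.77 ± 0.849 FPKM (log2 fold change -2.33, SE 0.205, adjusted p = 1.17e-06 in limma), and PROPEP3, the precursor of an immune peptide, from 12.1 ± 2.87 to 1.25 ± 0.532. With FRK1, 9 of 16 members of the immunity list were lower, 0 higher and 7 not called, with 10 called when adjusted over the list alone (median -0.56, camera adjusted p = 2.71e-09). In the touch and wounding list the transcription factor gene ZAT10 fell from 16.4 ± 1.5 to 1.66 ± 0.111 FPKM (-2.71, adjusted p = 4.16e-09). WRKY40 fell from 18.4 ± 2.61 to 1.64 ± 0.706, and the calcium-binding gene TCH3 from 217 ± 18.4 to 104 ± 7.44. There 8 of 12 members were lower, 0 higher and 4 not called, with 9 called when adjusted over the list alone (median -0.78, camera adjusted p = 3.33e-12). FRK1, WRKY40 and TCH3 overlap a locus on the opposite strand and are uncertain.

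Salicylic acid genes and immune receptor genes were also lower in nrpe1-11 in part. WRKY53, a transcription factor gene of the salicylic acid list, fell from 8.95 ± 1.57 to 1.59 ± 0.319 FPKM (log2 fold change -1.94, SE 0.17, adjusted p = 1.11e-06 in limma), ICS1, which makes most salicylic acid, from 7.38 ± 1.06 to 3.35 ± 0.637, and WRKY46 from 4.37 ± 1.83 to 1.01 ± 0.342. PR1, a pathogenesis-related protein gene, was the 1 member that rose (0.94, adjusted p = 0.00151), and it was picked after the values were seen. Of 23 members 10 were lower, 1 higher and 12 not called, with 12 called when adjusted over the list alone. The median was -0.48 (camera adjusted p = 3e-07, and adjusted p = 0.128 with an estimated correlation). Among immune receptors of the NLR type, RPP4 fell from 14.1 ± 1.79 to 7.37 ± 0.253 FPKM (-0.85, adjusted p = 0.000464), RMG1 from 2.25 ± 0.315 to 0.285 ± 0.102, and ZAR1 from 26.7 ± 0.235 to 19.4 ± 1.86. There 5 of 19 were lower, 0 higher and 14 not called, with 6 called when adjusted over the list alone. The median was -0.08 (camera adjusted p = 0.00495, and adjusted p = 0.288 with an estimated correlation). WRKY53 and ZAR1 overlap a locus on the opposite strand and are uncertain.

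Photosynthesis and leaf genes were lower and clock genes moved in opposite directions in nrpe1-11. LHCB3, another light-harvesting protein gene, fell from 589 ± 15.9 to 150 ± 6.32 FPKM (log2 fold change -1.97, SE 0.072, adjusted p = 6.33e-11 in limma). With LHCB1.1 and LHCB2.1, 13 of 15 members of that list were lower, 0 higher and 2 not called, with 14 called when adjusted over the list alone (median -0.74, camera adjusted p = 2.35e-23). CCA1, a morning clock gene, fell from 7.09 ± 0.376 to 0.645 ± 0.239 FPKM (-2.31, adjusted p = 1.47e-07), and PRR9 from 4.35 ± 1.13 to 0.503 ± 0.211. CCR2, whose RNA peaks in the evening, rose from 438 ± 19.1 to 889 ± 36.7 FPKM (1.02, adjusted p = 2.3e-07). Of 14 clock genes 7 were lower, 5 higher and 2 not called, with 12 called when adjusted over the list alone. The median was -0.22, and camera did not call the list (adjusted p = 0.13). In fry, which also tests movement in mixed directions, the mixed adjusted p was 1.76e-07, but the reference genes passed that test too (3.67e-05), so it did not single out the clock. Members picked after the values were seen also split: LHY (-1.16) and RVE8 (-1.52) fell, while TOC1 (0.79) and ELF4 (0.92) rose. LHCB3 overlaps a locus on the opposite strand and is uncertain.

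**Figure D2:**
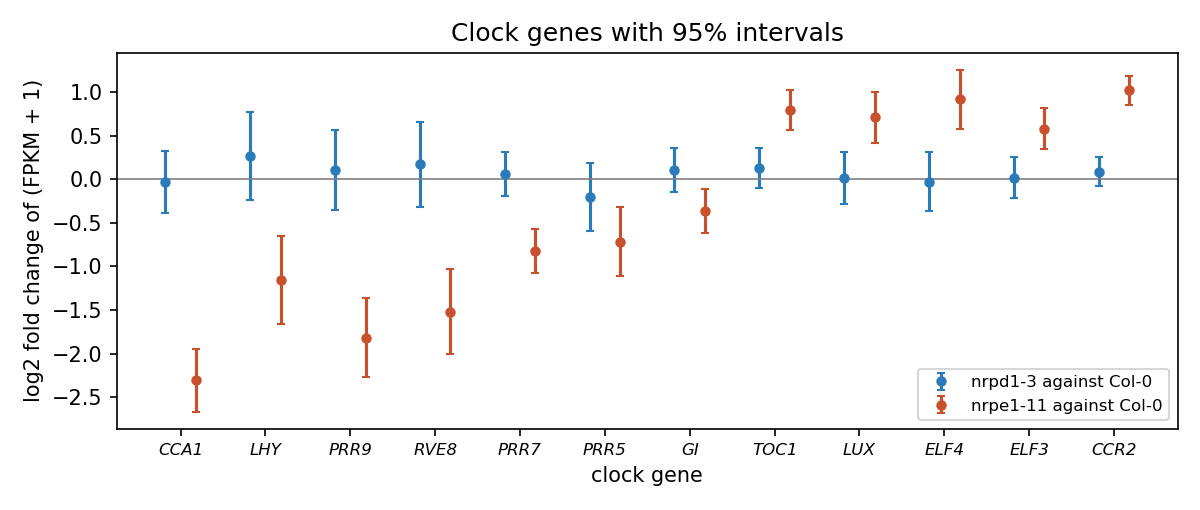
Log2 fold changes of the tested clock genes with 95% intervals in the compared genotypes (n = 3 libraries each).

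Genes of RNA-directed DNA methylation themselves changed little in nrpe1-11. NRPD1 rose from 0.703 ± 0.307 to 1.95 ± 0.370 FPKM (log2 fold change 0.80, SE 0.222, adjusted p = 0.019 in limma), and the RNA-binding gene IDN2 from 8.52 ± 0.817 to 11.9 ± 1.57 (0.43, adjusted p = 0.0345). The NRPD1 call was lost without Col-0 replicate 1 (0.75), Col-0 replicate 2 (0.71), nrpe1-11 replicate 2 (0.79) or nrpe1-11 replicate 3 (0.71). Relative to the median of all genes the rise of IDN2 was 0.26, and it was not called after median-ratio rescaling. The IDN2 call was also lost without Col-0 replicate 1 (0.44), Col-0 replicate 2 (0.37), nrpe1-11 replicate 1 (0.36) or nrpe1-11 replicate 3 (0.41). Of 17 members 2 were higher, 0 lower and 15 not called, with 1 called when adjusted over the list alone (median 0.28, camera adjusted p = 0.471). In the list for methylation maintenance and demethylation ROS1 fell and 8 of 9 members were not called, with 1 called when adjusted over the list alone. That list had a median of 0.18, a mean of 0.05 and a camera direction of down (adjusted p = 0.892), so these differed in sign. Of 4 tested genes on the list of silenced or methylation-sensitive genes, ROS1, whose RNA depends on methylation, RMG1 and QQS were called lower, and 3 were called when adjusted over the list alone. QQS, which acts on starch, was listed at 0 in each nrpe1-11 library and at 4.77, 1.38 and 3.39 FPKM in Col-0. Among 19 tested genes matched as transposable elements by annotation text, SADHU1-1 rose (0.52), SADHU3-2 (-1.26) and SADHU5-1 (-1.01) fell, and 16 were not called. These 3 were 15.8% of the group, against 21.7% of other genes (Fisher's exact test, p = 0.781). The group holds protein-coding genes with a transposase-type product, such as MUG3 and MUG7, beside pseudogenes. The test therefore does not describe silenced elements as such. SADHU1-1 overlaps a locus on the opposite strand and is uncertain.

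The remaining lists were not called by camera in nrpe1-11 against Col-0. In aliphatic glucosinolate synthesis MAM1 rose from 51.1 ± 2.1 to 82.8 ± 3.67 FPKM (log2 fold change 0.69, adjusted p = 3.64e-05 in limma), MAM3 rose (0.66) and SUR1 fell (-0.56), with 3 of 9 members higher and 2 lower, 7 called when adjusted over the list alone, and a camera adjusted p of 0.596. In the root list PHO1, a phosphate exporter gene, rose from 21.9 ± 1.83 to 36.0 ± 0.607 FPKM (0.69, adjusted p = 0.00014), with 4 of 9 members higher and 1 lower, 6 called when adjusted over the list alone, and a camera adjusted p of 0.138. In flowering time MAF5 (1.76) and SPL3 (0.78) rose, 2 of 6 members, also 2 when adjusted over the list alone (camera adjusted p = 0.246). In leaf senescence SAG13 fell from 19.2 ± 0.994 to 2.96 ± 0.175 FPKM and SAG21 rose from 317 ± 15.0 to 523 ± 10.7, with 2 of 5 higher and 1 lower, and 3 called when adjusted over the list alone. That list had a median of 0.24, a mean of -0.24 and a camera direction of down (adjusted p = 0.809). In heat shock HSP18.2 rose (1.21), 1 of 6 members, also 1 when adjusted over the list alone (camera adjusted p = 0.906). The flavonoid gene CHS fell from 7.02 ± 0.862 to 1.44 ± 0.221 FPKM, 1 of 5 members, also 1 when adjusted over the list alone (camera adjusted p = 0.0684). The phosphatase gene PS2 fell (-1.09), 1 of 5 members of the phosphate list, also 1 when adjusted over the list alone (camera adjusted p = 0.138). SPL3 and CHS overlap a locus on the opposite strand and SAG21 on the same strand, so they are uncertain.

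A few members of these lists had calls near the threshold, which were lost when 1 library was left out, mostly with little change in the value. The potassium channel gene AKT1 rose by 0.45 in nrpe1-11, and its call was lost without nrpe1-11 replicate 2 (0.45). The glucosidase gene PYK10 rose by 0.42, and its call was lost without Col-0 replicate 2 (0.28) or nrpe1-11 replicate 3 (0.40). In the cold and abscisic acid list KIN2 fell (-1.01) and COR47 rose (0.40), 1 of 7 members each way, with 2 called when adjusted over the list alone (camera adjusted p = 0.375), and the COR47 call was lost without nrpe1-11 replicate 3 (0.35). In the iron list the transporter gene IRT1 fell (-0.80) and the ferritin gene FER1 rose (0.27), 1 of 6 members each way, with 3 called when adjusted over the list alone (camera adjusted p = 0.596). The IRT1 call was lost without Col-0 replicate 2 (-0.71), Col-0 replicate 3 (-0.82), nrpe1-11 replicate 1 (-0.58) or nrpe1-11 replicate 2 (-0.81). The FER1 call was lost without Col-0 replicate 2 (0.23), Col-0 replicate 3 (0.29), nrpe1-11 replicate 1 (0.30), nrpe1-11 replicate 2 (0.26) or nrpe1-11 replicate 3 (0.25). The senescence gene SEN1 rose (0.37), and its call was lost without Col-0 replicate 2 (0.30), nrpe1-11 replicate 2 (0.29) or nrpe1-11 replicate 3 (0.33). Relative to the median of all genes, the rises of AKT1, PYK10, COR47, SEN1 and FER1 were 0.28, 0.24, 0.23, 0.19 and 0.10, and none of them was called after median-ratio rescaling. PYK10, AKT1 and FER1 overlap a locus on the opposite strand and are uncertain.

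Genes commonly used as references were not level in nrpe1-11. ACT8 rose from 126 ± 10 to 189 ± 1.60 FPKM (log2 fold change 0.58, SE 0.081, adjusted p = 0.000125 in limma), ACT2 rose from 243 ± 16.8 to 329 ± 6.87 (0.44), and GAPC1 fell from 151 ± 2.80 to 117 ± 3.49 (-0.36). Relative to the median of all genes these were 0.41, 0.27 and -0.54, and each kept its direction under the other scalings. Of 8 members 3 were higher, 1 lower and 4 not called, with 5 called when adjusted over the list alone (median 0.27, camera adjusted p = 0.471). Camera called 7 of 20 tested lists, all with lower values in nrpe1-11. With an estimated correlation 5 of these were called: jasmonate and ethylene (adjusted p = 0.00786), camalexin and indole glucosinolate (0.0127), photosynthesis and leaf (0.0199), touch and wounding (0.0199) and pattern-triggered immunity (0.032). Fry, which tests for movement in 1 direction and not against other genes, called 14.

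**Figure D3:**
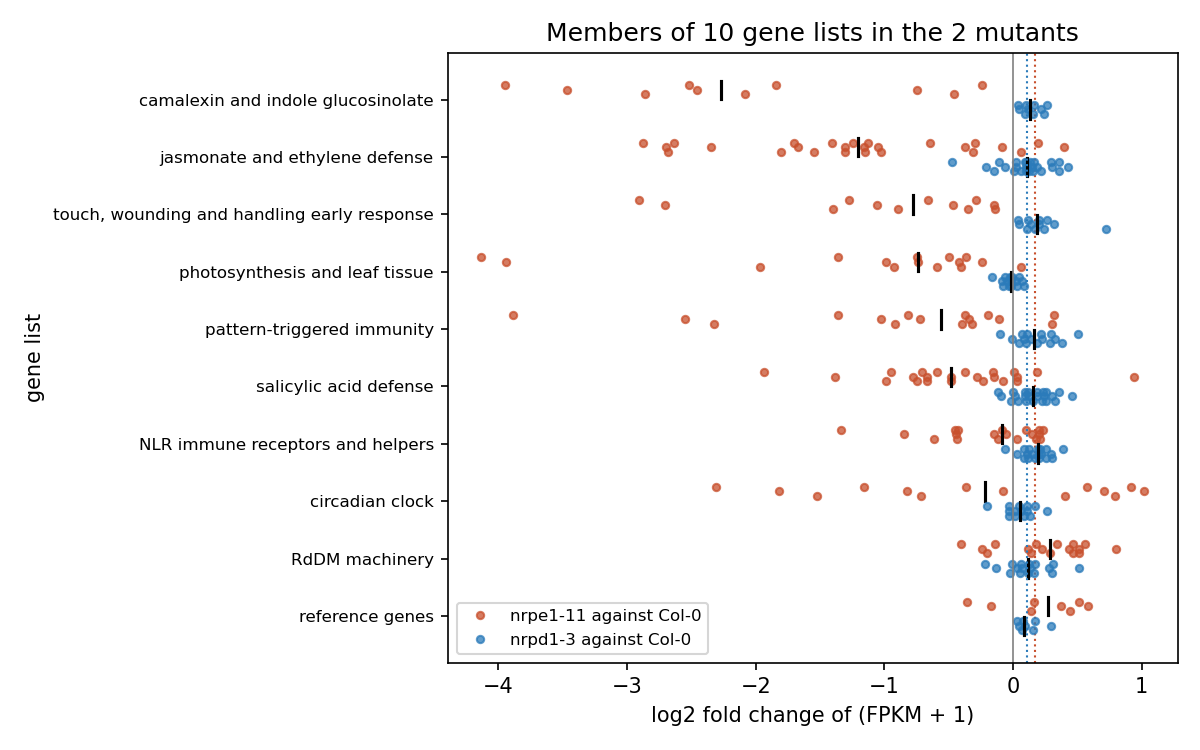
Log2 fold changes of the members of 10 gene lists in nrpe1-11 and in the libraries labelled nrpd1-3 against Col-0, with list medians as black bars.

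The comparison of the libraries labelled nrpd1-3 with Col-0 asked which RNAs differ when the RNA polymerase IV subunit is mutated, as far as the label holds. No gene passed: limma called 0 of 18212 genes (smallest adjusted p = 0.681), with 1284 at an unadjusted p under 0.05 where 911 are expected by chance. That count was 955 after median-ratio rescaling and 941 after quantile normalization. In limma it was 699 without Col-0 replicate 2, 761 without nrpd1-3 replicate 1, 738 without nrpd1-3 replicate 3 and 2139 without nrpd1-3 replicate 2. It was 1725 without Col-0 replicate 1, 1723 without Col-0 replicate 3 and 1718 with a replicate block, so it lay below or above the chance count depending on the setting. The libraries did not overlap in 2130 genes, or 11.7%, where chance gives 10%. The 6 genes with the smallest p-values had an adjusted p of 0.681 each. AT2G05225, an uncharacterized RNA, had 3.73 ± 1.18 FPKM in nrpd1-3 and 7.95 ± 0.976 in Col-0. AT4G08555, of unknown function, had 13.4 ± 0.961 and 7.14 ± 0.955, the uncharacterized RNA AT1G09605 2.29 ± 0.664 and 0.535 ± 0.368, and the Cornichon family gene AT1G12340 1.79 ± 0.408 and 0.226 ± 0.391. The small nucleolar RNA AT2G04965 had 1.73 ± 1.29 FPKM in nrpd1-3 and 8.14 ± 1.98 in Col-0. AT4G18740, which overlaps a locus on the opposite strand, had 24.5 ± 2.66 and 15.6 ± 3.10. The 95% interval of a gene's log2 fold change reached 0.37 to each side (median) before any adjustment. In the simulated comparison of nrpe1-11 with Col-0, 20 of 67 genes changed by 0.5 were recovered, so changes well above 0.37 can also be missed among 0 calls in limma. Those simulated genes left out low expression, and other genes were changed too, which eases the adjusted threshold. The rate therefore describes neither low genes nor the nrpd1-3 comparison itself. Limma with robust variances, without the expression filter, and after each other scaling likewise called 0 genes.

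No member of any list was called in the libraries labelled nrpd1-3 (0 in limma), and the members with the smallest p-values are given as values. RDR2, the RNA-dependent RNA polymerase that works with RNA polymerase IV, had 1.78 ± 0.247 FPKM in nrpd1-3 and 0.954 ± 0.164 in Col-0 (log2 fold change 0.51, SE 0.196, adjusted p = 0.681), and the chromomethylase gene CMT2 had 3.23 ± 0.374 and 2.22 ± 0.245. The genes PDF1.2C (0.36), HR4 (0.30), MAM1 (-0.13) and HSP18.2 (0.56) had small differences, as had LHCB1.1 (-0.16), PHO1 (0.25), SAG21 (0.13), BHLH39 (-0.35) and UBC21 (0.30). Several values moved with single libraries. QQS (-0.51) was -0.23 without Col-0 replicate 1, -0.87 without Col-0 replicate 2, -0.85 without nrpd1-3 replicate 1 and -0.31 without nrpd1-3 replicate 3. CBP60G (0.32) was 0.19 without nrpd1-3 replicate 3. MYB51 (0.26), FLS2 (0.33), TOC1 (0.13) and SOC1 (0.37) were 0.16, 0.13, 0.04 and 0.18 without Col-0 replicate 2. RAB18 (-0.32) was -0.17 without nrpd1-3 replicate 1 and -0.49 without nrpd1-3 replicate 3. FLS1 (0.43) was 0.66 without nrpd1-3 replicate 2 and 0.29 without nrpd1-3 replicate 3. SPX1 (0.20) was 0.00 without Col-0 replicate 2 and without nrpd1-3 replicate 1, 0.33 without Col-0 replicate 3 and 0.35 without nrpd1-3 replicate 2. When adjusted over the list alone, CML38 of the touch list, with 8.24 ± 1.21 and 4.67 ± 1.37 FPKM, was the 1 member called in any list. FLS2, RAB18 and UBC21 overlap a locus on the opposite strand and SAG21 on the same strand, so they are uncertain.

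Among lists, camera called 1 in nrpd1-3 against Col-0, photosynthesis and leaf genes, with a median of -0.02 (adjusted p = 0.0292). That call was absent with an estimated correlation (adjusted p = 0.897 with an estimated correlation) and in fry (adjusted p = 0.686). The camera adjusted p was 0.579 without Col-0 replicate 2, 0.1 without Col-0 replicate 3, 0.289 without nrpd1-3 replicate 1 and 0.298 without nrpd1-3 replicate 3. The list's median was -0.15 after median-ratio rescaling (adjusted p = 1.8e-05). None of the 19 genes matched as transposable elements was called (0 in limma). Camera compares a list with the other genes, whose median lay above 0, so lists such as jasmonate and ethylene (median 0.10) and the clock (0.05) had a direction of down with a median above 0. The median and mean differed in sign for the phosphate list (-0.02 and 0.04) and for the silenced or methylation-sensitive genes (0.06 and -0.07).

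The comparison of nrpe1-11 with nrpd1-3 asked which RNAs differ between the mutants, and it uses the libraries labelled nrpd1-3 as given. FRK1 fell to 0.381 ± 0.337 FPKM in nrpe1-11 from 23.4 ± 1.85 in nrpd1-3 (log2 fold change -4.17, SE 0.187, adjusted p = 6.03e-10 in limma). GSTF6 fell to 28.5 ± 0.660 from 512 ± 41.8 (-4.12, adjusted p = 5.34e-13), and LHCB2.1 to 16.1 ± 1.05 from 282 ± 14.3 (-4.05, adjusted p = 3.61e-13). CYP71A13 (-4.11), the chitinase gene AT2G43620 (-4.09), AT1G26380 (-3.93) and the lipid transfer type gene AT4G12500 (-3.87) fell as well, and the lectin gene AT3G15356 fell to 17.2 ± 2.23 from 248 ± 10.3 FPKM. The largest rises were AT4G02795 (4.07), AT1G67105 (2.47), AT5G41830 (2.42, 5.42 against 0.210 FPKM), KELP (1.93), the defensin gene PDF1.5 (1.84), the MADS-box gene AT1G59930 (1.62), AT5G63250 (1.57) and the noncoding RNA AT2G01422 (1.56). In each of these 16 genes the libraries of the mutants did not overlap, which the rule that named them required. FRK1, CYP71A13, AT4G02795 and KELP overlap another locus and are uncertain.

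Between the mutants, 2679 of 18212 genes (14.7%) were called in limma, 1128 higher and 1551 lower in nrpe1-11. Of these 703 changed at least 2-fold, 61 higher and 642 lower, and 136 at least 4-fold, 3 higher and 133 lower. The libraries did not overlap in 6097 genes, or 33.5%, where chance gives 10%. The number of genes called higher was 668 without nrpe1-11 replicate 3, 723 without nrpe1-11 replicate 2 and 684 without nrpd1-3 replicate 2. It was 1582 without Col-0 replicate 2. The share of called genes that were higher in nrpe1-11, 42.1%, was 34.6% after median-ratio rescaling (1066 higher, 2014 lower), 45.3% after quantile normalization (1492 and 1801), 51.8% after scaling to the protein-coding sum (1800 and 1673) and 31.6% without nrpd1-3 replicate 2. This comparison equals the difference between the changes of nrpe1-11 and of nrpd1-3 against the shared Col-0 libraries.

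Defense lists were lower in nrpe1-11 than in nrpd1-3. LOX2 fell to 5.22 ± 0.275 from 47.7 ± 1.36 FPKM (log2 fold change -2.97, SE 0.099, adjusted p = 1.83e-11 in limma), PDF1.2C to 0.928 ± 0.157 from 14.8 ± 0.758 and AOC2 to 5.40 ± 1.16 from 43.2 ± 1.46. In the jasmonate and ethylene list 21 of 26 were lower and 0 higher, also 21 when adjusted over the list alone (median -1.22, camera adjusted p = 9.57e-22). CYP71A12 (-3.57) and CYP79B2 (-2.50) fell, and 9 of 10 camalexin and indole glucosinolate genes were lower, 10 when adjusted over the list alone (median -2.42, camera adjusted p = 1.09e-21). NHL10 (-2.55) and PROPEP3 (-3.05) fell, and 9 of 16 genes of pattern-triggered immunity were lower, 11 when adjusted over the list alone (median -0.78, camera adjusted p = 1.49e-09). ZAT10 (-2.91), WRKY40 (-3.01) and TCH3 (-1.26) fell, and 11 of 12 touch and wounding genes were lower, also 11 when adjusted over the list alone (median -1.04, camera adjusted p = 1.88e-13). In the salicylic acid list WRKY53 (-2.17), WRKY46 (-1.84) and the calmodulin-binding regulator CBP60G (-1.1) fell, with 11 of 23 lower and 1 higher, 15 when adjusted over the list alone (camera adjusted p = 1.25e-07, and adjusted p = 0.115 with an estimated correlation). RPP4 (-1.1), RMG1 (-1.36) and ZAR1 (-0.55) fell among immune receptors, with 8 of 19 lower, also 8 when adjusted over the list alone (median -0.20, camera adjusted p = 0.000139, and adjusted p = 0.18 with an estimated correlation). WRKY53, ZAR1, TCH3 and WRKY40 overlap a locus on the opposite strand and are uncertain.

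Photosynthesis genes were lower in nrpe1-11 than in nrpd1-3 as well. LHCB1.1 fell to 62.4 ± 4.67 from 868 ± 11.2 FPKM (log2 fold change -3.78, SE 0.079, adjusted p = 2.13e-13 in limma) and LHCB3 to 150 ± 6.32 from 578 ± 0.809, with 14 of 15 members of the photosynthesis and leaf list lower, also 14 when adjusted over the list alone (median -0.71, camera adjusted p = 6.12e-21). CCA1 (-2.27) and PRR9 (-1.92) fell and CCR2 (0.94) rose, with 6 of 14 clock genes lower and 5 higher, 12 when adjusted over the list alone (camera adjusted p = 0.369). CHS fell to 1.44 ± 0.221 from 7.16 ± 0.380 FPKM, 1 of 5 flavonoid genes, 2 when adjusted over the list alone (median -0.44, camera adjusted p = 0.0221, and adjusted p = 0.176 with an estimated correlation). ROS1 fell by 1.43 on the log2 scale (adjusted p = 3.27e-05), with 1 of 9 genes for methylation maintenance and demethylation lower, also 1 when adjusted over the list alone. ROS1, RMG1 and QQS, 3 of 4 silenced or methylation-sensitive genes, were called lower, also 3 when adjusted over the list alone, with QQS listed at 0 in each nrpe1-11 library and at 3.41, 1.27 and 1.1 FPKM in nrpd1-3. Among the genes matched as transposable elements 3 of 19 were called, with SADHU1-1 and Sadhu4-2 higher and SADHU5-1 lower. They were 15.8% of the group, against 14.7% of other genes (Fisher's exact test, p = 0.752). Camera called 8 of 20 lists here, all lower in nrpe1-11, and fry called 12. With an estimated correlation 5 were called: jasmonate and ethylene (adjusted p = 0.00983), camalexin and indole glucosinolate (0.0138), touch and wounding (0.0206), photosynthesis and leaf (0.0217) and pattern-triggered immunity (0.0299). LHCB3, CHS and SADHU1-1 overlap a locus on the opposite strand and Sadhu4-2 on each strand, so they are uncertain.

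Other members called between the mutants lay in small lists. MAM1 rose to 82.8 ± 3.67 from 46.5 ± 0.536 FPKM (log2 fold change 0.82, adjusted p = 5.31e-06 in limma), MAM3 rose (0.50) and SUR1 fell (-0.69). SAG21 (0.60), SPL3 (0.84), MAF5 (1.56) and PHO1 (0.45) rose and SAG13 (-2.39) fell. ACT8 (0.50) and ACT2 (0.40) rose and GAPC1 (-0.46) fell. Of the genes for RNA-directed DNA methylation, NRPD1 rose (0.74, adjusted p = 0.0361) and NRPE1 fell (-0.71, adjusted p = 0.0365), 2 of 17 members. The NRPD1 call was lost without nrpd1-3 replicate 1 (0.70), nrpd1-3 replicate 2 (0.70), nrpd1-3 replicate 3 (0.81), nrpe1-11 replicate 2 (0.72) or nrpe1-11 replicate 3 (0.65). The NRPE1 call was lost without nrpe1-11 replicate 2 (-0.63) or nrpe1-11 replicate 3 (-0.68). HSP17.6A of the heat shock list, with 1.4 ± 0.363 and 0.379 ± 0.166 FPKM, was not called (0.80, adjusted p = 0.055), but was called without Col-0 replicate 1 (0.80) or Col-0 replicate 2 (0.80). SPL3 overlaps a locus on the opposite strand and SAG21 on the same strand, so they are uncertain.

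Several list members called between the mutants lay near the threshold and lost their call when 1 library was left out, some with no smaller value. The cold gene KIN2 fell (-0.97), and its call was lost without nrpd1-3 replicate 1 (-0.81), nrpd1-3 replicate 2 (-0.81) or nrpe1-11 replicate 2 (-0.83). The expansin gene EXPA7 rose (0.87), and its call was lost without nrpd1-3 replicate 3 (0.78), nrpe1-11 replicate 1 (0.86) or nrpe1-11 replicate 3 (0.85). For FIT, a regulator of iron uptake that rose (0.65), the same held without nrpd1-3 replicate 1 (0.50), nrpe1-11 replicate 2 (0.51) or nrpe1-11 replicate 3 (0.67). For SOC1, a flowering regulator that fell (-0.57), it held without nrpd1-3 replicate 1 (-0.47), nrpe1-11 replicate 1 (-0.54) or nrpe1-11 replicate 3 (-0.57). PS2 fell (-1.02) and lost its call without nrpd1-3 replicate 1 (-0.94), nrpd1-3 replicate 2 (-0.90) or nrpe1-11 replicate 3 (-0.77). PHT1;4, a phosphate transporter gene, fell (-0.54) and lost its call without Col-0 replicate 1 (-0.54), Col-0 replicate 3 (-0.54), nrpd1-3 replicate 1 (-0.56), nrpd1-3 replicate 2 (-0.43), nrpd1-3 replicate 3 (-0.61), nrpe1-11 replicate 1 (-0.58), nrpe1-11 replicate 2 (-0.53) or nrpe1-11 replicate 3 (-0.50). In the lists of these genes, 1 of 7 cold and abscisic acid genes was called (2 when adjusted over the list alone), 2 of 9 root genes (4), 1 of 6 iron genes (2), 3 of 6 flowering genes (3) and 2 of 5 phosphate genes (2). Of the other lists, 5 of 9 aliphatic glucosinolate genes were called (5 when adjusted over the list alone), 2 of 5 senescence genes (3), 0 of 6 heat shock genes in limma (2), 3 of 8 reference genes (3) and 2 of 17 genes for RNA-directed DNA methylation (2). The median and mean differed in sign for methylation maintenance and demethylation (0.06 and -0.07), for senescence (0.21 and -0.34) and for iron (-0.00082 and 0.03). EXPA7 overlaps a locus on the opposite strand and is uncertain.

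The last comparison set the changes of nrpe1-11 and nrpd1-3 against Col-0 side by side and asked whether they were shared. No gene was called in both (0 in limma, because 0 were called in nrpd1-3). ROS1 fell by 1.33 on the log2 scale in nrpe1-11 and had 0.10 in nrpd1-3, LHCB2.1 fell to 16.1 ± 1.05 FPKM in nrpe1-11 and had 282 ± 14.3 in nrpd1-3 beside 298 ± 28.9 in Col-0, and GSTF6 fell to 28.5 ± 0.660 and had 512 ± 41.8 beside 440 ± 57.1. Among the 660 genes changed at least 2-fold in nrpe1-11, the 95% interval of the nrpd1-3 change excluded the full nrpe1-11 change in 95.3% and 0.5 of it in 79.5%. In the direction of the nrpe1-11 change, the median nrpd1-3 change of these genes was -0.06, beside a median size of 1.36 in nrpe1-11. Across all tested genes the changes correlated at 0.234. Both rest on the same 3 Col-0 libraries, and simulated libraries without any effect gave 0.501. The covariance was 0.0219, beside 0.0184 simulated, and 67.1% of genes had the same sign, beside 66.7% simulated. The 3 Col-0 libraries were not divided between the mutants to remove this sharing, and no shared effect is read from these values.

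**Figure D4:**
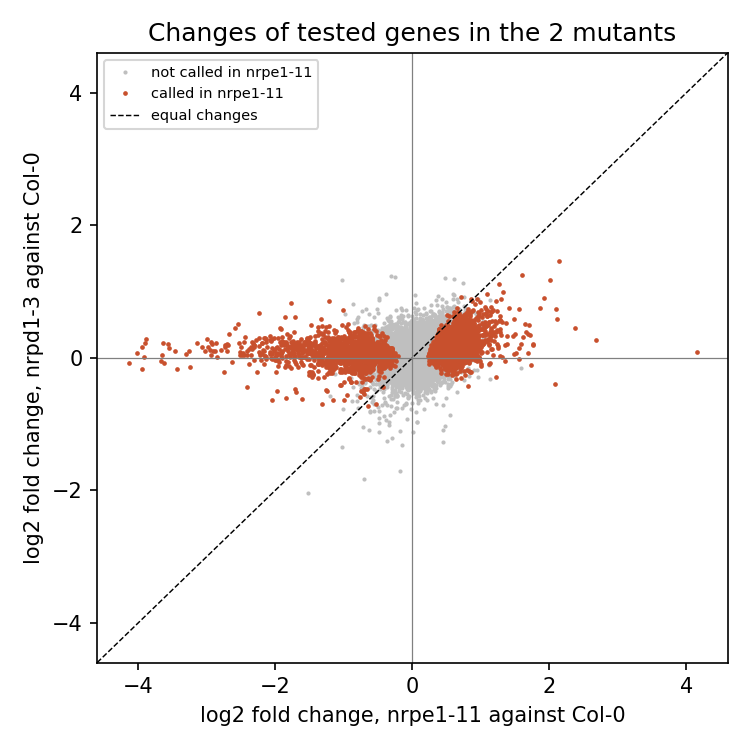
Log2 fold changes of the tested genes in nrpd1-3 and in nrpe1-11 against Col-0, with genes called in nrpe1-11 coloured.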

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

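The tests in this part were chosen only after the result was seen, except the time-of-day markers, which were chosen after the clock list had been seen but before their own values were. The changes of nrpe1-11 and of the libraries labelled nrpd1-3 differed: 2679 genes were called between the mutants, and ROS1, the DNA demethylase gene, differed by -1.43 on the log2 scale (0.991 ± 0.110 FPKM in nrpe1-11, 4.36 ± 0.115 in nrpd1-3, n = 3 each). Groups of 3 libraries were not tested for outlying libraries.

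No gene was called between the libraries labelled nrpd1-3 and Col-0 (0 of 18212 in limma, 1284 at an unadjusted p under 0.05, but 955 after median-ratio rescaling, 699 without Col-0 replicate 2, 1725 without Col-0 replicate 1 and 2139 without nrpd1-3 replicate 2). A technical explanation is too little precision. Among the 660 genes called and changed at least 2-fold in nrpe1-11, the nrpd1-3 interval excluded the nrpe1-11 change in 95.3%. Most of them therefore did not change alike in nrpd1-3. These genes were chosen because they passed in the same fit, where a gene has the same SE in each comparison. Enough precision was thus largely built in for them, and the value does not test precision for other genes or smaller changes. Another explanation is that the plants sampled under this label did not carry the nrpd1 defect: ROS1 would then not fall, the 95% interval of its change had a lower bound of -0.275, and NRPD1 RNA was not lower, so this explanation could not be excluded, although a mutant allele can keep its RNA. A biological difference between the polymerases stays open as well, and genotyping by sequence, which was not analysed here, would separate them.

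Clock genes split (7 lower, 5 higher, not called by camera), and leaf and defense lists were lower, in the same nrpe1-11 libraries, and joint movement was not tested. Later collection in the day was tested with 13 time-of-day markers outside the list: 11 lay on the side that a later hour needs, 9 were called, and 0 were called on the opposite side (LNK1, LNK3, COL1 and COL2 overlap another locus and are uncertain). Sides were taken relative to the median change of all genes. CDF2, a morning gene, counts among the 11 only in that way, with a change of 0.12 but -0.06 relative to that median. LNK3 (-2.80), LNK1 (-1.91), CDF3 (-1.76), SIG5 (-1.54), COL1 (-1.21) and COL2 (-0.84), which are morning genes, fell, and JMJ30 (1.24), PRR3 (0.69) and CCR1 (0.52), which peak later, rose. A lower share of leaf tissue alone would lower leaf genes alike, but 12 of 15 members had a 95% interval that excluded the list median, from LHCB2.1 (-4.13) to GAPA (0.06, overlapping another locus). That goes against leaf share as the only cause, but cannot exclude a part of it, because other changes could add to it. Root genes were higher in 4 of 9 and lower in 1 (median 0.415, camera adjusted p = 0.138). By the 13 markers, a later hour of collection could account for part of the clock values. The markers do not show whether it also lowered the leaf and defense lists, so a later hour is not excluded for them. A genotype effect on clock phase would give the same markers, and the hour of collection is not in the labels.

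More genes were called higher than lower in nrpe1-11 against Col-0 (65.3% of 3955). The scaling of the deposited values could produce this, because 35.3% were higher after median-ratio rescaling. An uneven share of ribosomal RNA could not by itself, because 60.7% were still higher after scaling to the protein-coding sum. The excess of small rises is therefore possibly a matter of scale. Falls of at least 2-fold were the larger group under the deposited scaling (534, against 126 rises). The same held after median-ratio rescaling (682 against 72), quantile normalization (612 against 85) and scaling to the protein-coding sum (572 against 108).

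Whether other groupings of the same libraries gave as many calls was examined by splitting the 6 libraries of each comparison in each of 10 ways. The number of splits that called as many genes as the real one, the real one included, was 1 of 10 for nrpe1-11 against Col-0 (3955 genes, highest other split 0), 10 of 10 for nrpd1-3 against Col-0 (0 genes, highest other split 1) and 1 of 10 for nrpe1-11 against nrpd1-3 (2679 genes, highest other split 0). With 10 splits this design cannot reach a share under 0.05. The 10 of 10 was fixed in advance, because no split can call fewer than 0 genes. In the comparisons with nrpe1-11, a mixed split leaves the genotype difference in the spread within groups, so low counts there are partly built in. No conclusion is drawn from these splits.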

How the results depend on the processing

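The alternatives were fixed before the data were examined, except the protein-coding sum rescaling, which was chosen only after the result was seen. No called gene was called in the opposite direction in any setting run, and genes that lost their call were not counted there. After median-ratio rescaling 2554 of the 3955 genes called in nrpe1-11 against Col-0 kept their call. Genes called in nrpe1-11 against Col-0 numbered 2758 to 4131 with 1 library left out, and 1982 to 3340 in nrpe1-11 against nrpd1-3. In nrpd1-3 against Col-0 there were 0 in every setting, with 1685 at an unadjusted p under 0.05 in limma without the filter. A threshold of at least 2-fold left 660 of 3955 and 703 of 2679 genes, fewer by its construction. With the replicate number as a replicate block the calls were 4428, 0 and 2996. Same-number libraries had residual correlations of -0.072 to 0.146 and others -0.124 to 0.07, ranges that overlap. Between Col-0 and nrpd1-3 the same-number values were 0.061, 0.146 and 0.021 for replicates 1, 2 and 3. Pairing by number is therefore neither shown nor excluded. Lists called by camera in nrpe1-11 against Col-0 were 7, and 11 without the filter and 14 in fry; the cause was not tested. In nrpd1-3 against Col-0 the 1 list was 0 without the filter, 0 after quantile normalization, 0 with an estimated correlation, 0 in fry and 0 to 1 with 1 library left out (0 without Col-0 replicate 2, 1 without Col-0 replicate 1); the cause was not tested. In nrpe1-11 against nrpd1-3 the 8 lists were 5 with an estimated correlation; the cause was not tested. Of the named genes AKT1, COR47, IDN2, FER1, PYK10 and SEN1 lost their call in nrpe1-11 against Col-0 after median-ratio rescaling (0.27, 0.21, 0.26, 0.08, 0.23 and 0.18). Without the filter AT5G23115, KIN2, COR47, PYK10, SEN1 and IRT1 lost theirs, as did QQS, KIN2, EXPA7, SOC1, FIT and PS2 in nrpe1-11 against nrpd1-3. There NRPE1 lost its call with a pseudocount of 0.1 (-1.52), after quantile normalization (-0.60) and with only the 6 libraries compared (-0.71), NRPD1 with a pseudocount of 0.1 (1.24), FIT after median-ratio rescaling (0.59) and PHT1;4 after quantile normalization (-0.53) and with only the 6 libraries compared (-0.54). IDN2 and FER1 also lost theirs in nrpe1-11 against Col-0 after quantile normalization (0.30 and 0.12), and FER1 with only the 6 libraries compared (0.27). PYK10, EXPA7, AKT1 and FER1 overlap another locus and are uncertain. Depth limits genes near an FPKM of 1, such as NRPD1 and NRPE1.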

Other observations

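The group tests in this part were chosen only after the result was seen, and no list for them was fixed before. Fisher's exact test counted each gene as separate, although genes of a group can move together, so its p-values may be too small. Genes of the annotation types ncRNA and snRNA were higher more often than other genes in nrpe1-11 against Col-0, and those of the types lncRNA, snoRNA and miRNA were not. Among the ncRNA genes AT1G67105 rose from 8.82 ± 3.14 to 39.4 ± 5.02 FPKM (log2 fold change 2.08, adjusted p = 6.06e-06 in limma). AT2G14878 rose from 38.6 ± 4.84 to 79.8 ± 0.941 FPKM (1.04), and TAS2, a precursor of trans-acting small RNAs, by 0.65. The other ncRNA genes of that name, TAS1A (0.39), TAS1B (0.62), TAS1C (-0.22) and TAS3 (0.10), were not called. Of 87 tested genes of the type ncRNA 27 were higher, 31.0% against 14.1% of all other tested genes (Fisher's exact test, adjusted p = 0.00082). Of 152 genes of the type lncRNA 16 were higher (10.5%), of 81 snoRNA genes 6 (7.41%) and of 26 miRNA genes 1 (3.85%), and over all genes that do not code for protein 13.9% were higher, against 14.2% of protein-coding genes. The share of the type ncRNA was 26.1% after median-ratio rescaling (6.42% of other genes) and 26.4% after quantile normalization (8.84% of other genes). It was 25.9% without Col-0 replicate 2. Of 9 genes of the type snRNA, the spliceosomal RNAs, 5 were higher (Fisher's exact test, adjusted p = 0.0262), each of them a U2 copy that overlaps another locus. Copies of 1 RNA can share reads, so these 5 may not be separate rises, although the test counted them as separate genes. In nrpe1-11 against nrpd1-3, 16 of 87 ncRNA genes were higher (adjusted p = 0.000926) and 2 of 9 snRNA genes (adjusted p = 0.354, Fisher's exact test).

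Among 217 gene families with at least 10 tested members, 8 of 434 tests passed in nrpe1-11 against Col-0, and some of the families are given. Members of a family can move together, which Fisher's exact test does not allow for, so these p-values may be too small. Cysteine-rich receptor kinase genes were lower in 13 of 26 (Fisher's exact test, adjusted p = 2.16e-06), with CRK11 at -1.52 and CRK10 at -1.48, and in 16 of 26 after median-ratio rescaling. Berberine-bridge type oxidase genes were lower in 11 of 18 (adjusted p = 2.16e-06), also 11 after median-ratio rescaling. WRKY genes were lower in 11 of 38 (Fisher's exact test, adjusted p = 0.0101) and higher in 8, and after median-ratio rescaling lower in 14 and higher in 2. Ubiquitin-like genes were higher in 10 of 22 (Fisher's exact test, adjusted p = 0.0245), among them ATG8B (0.84) and APG8A (0.70), and in 5 after median-ratio rescaling (Fisher's exact test, unadjusted p = 0.0121 among 434 tests). In nrpe1-11 against nrpd1-3 they were higher in 2 of 22 (adjusted p = 0.988), while cysteine-rich receptor kinase genes were lower in 15 of 26, berberine-bridge type oxidase genes in 11 of 18 and WRKY genes in 10 of 38 (adjusted p = 1.15e-07, 6.5e-06 and 0.029). CRK10, CRK11 and APG8A overlap a locus on the opposite strand and are uncertain.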
